A study of Arabidopsis thaliana with 3 samples.

How the data were processed

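RNA from the vascular tissue of Arabidopsis thaliana cotyledons was measured on Affymetrix Arabidopsis Gene 1.0 ST arrays, which carry sets of short probes for annotated genes. The 3 arrays hold wild type on plain medium, wild type on medium with the peptide CEP1, and the mutant cepr1-1 on plain medium, with 1 array per group. The labels' protocols describe 8 days of growth, enzyme and sonication treatment of the cotyledons, and collection of the vascular strands by hand under a microscope. Each RNA came from 200 cotyledons, so biological differences between plants were averaged within an array and not measured.

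The deposited values are log2 probe set values, 1 per probe set and array; the log scale was read from their range, since no header names it. They were made with Affymetrix Expression Console 1.3, per the submitters' processing notes. The background correction, the normalization and the way probes were summarised are not given in the sources used here. The medians over measured genes were 3.07 for the control, 3.07 for the CEP1 array and 3.11 for cepr1-1, so the arrays share a scale, and no further normalization was applied for the main values. The number of arrays limits the precision, and signal over background cannot be given because the table holds no background values.

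Of 38408 probe sets, the platform annotation used here lists 17481. It gives 1 gene for 16722 of them, several genes for 759 (not used) and no entry for 20927, which are unnamed here. Current names were taken from the RefSeq gene table of the TAIR10.1 assembly. There, 16574 probe sets matched by gene ID, 96 by locus only and 52 did not match. After the probe set with the highest mean was kept for each locus, 16505 measured genes remained, of which 1762 have a symbol other than the locus. The array's genome build is not given in the sources used here, so no coordinates are printed and the assembly served only for names and for which genes neighbour each other. CEPR1, CEPR2 and CEP1 have no named probe set here and were not analysed.

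A difference is the log2 value of the CEP1 or cepr1-1 array minus that of the control array, and a fold is 2 to the power of its size. With 1 array per group there is no test, so genes are described by a fixed rule of size: 2-fold or more in 1 comparison, or 1.5-fold or more in both. A gene counts as above the floor in a comparison if the brighter of its 2 arrays is at or above that array's median over measured genes. Both comparisons use the same control array. As a reference in which the 3 arrays are exchangeable, the 3 values of each gene were permuted 1000 times. Permuting keeps any real differences and shuffles which array carries them, so it is not what a shared control alone gives. The number expected from independent lists was computed as the product of the list sizes over the genes tested.

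Named genes follow a rule set before the data were examined. It takes the 12 largest positive and 12 largest negative differences above the floor per comparison, the CEP and receptor genes, the 4 CEPD or CEPD-like glutaredoxins, the 10 genes with the largest differences of opposite sign in both comparisons and the 10 of the same sign, and up to 4 members of each fixed list that stood apart or up to 2 of the others. The 12 largest were read in a pair of ways, over all genes and over genes with a symbol, and the genes with a symbol were named at 2-fold or more. AT3G62930, the tandem glutaredoxin copies, EXPA9, APS3 and CLE41 fall outside the rule and were chosen after their values were seen. Cell type lists cover phloem, xylem and procambium, mesophyll, and epidermis and guard cells.

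There were 28 fixed lists with 380 different genes, of which 69 are measured under a name here. A list with at least 3 measured members was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and stands apart if its median lies outside the central 95% of these. This applied to 9 lists, another 10 had 1 or 2 measured members and 9 had none. The lists with no measured member, which were not analysed here, are nitrogen assimilation, amino acid transporters, xylem and procambium, phosphate starvation, ferritins, jasmonate, salicylate and defence, senescence and cell division.

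On simulated values for the 16505 genes, with 200 genes changed by known folds, the 2-fold rule found 100% of the 50 genes planted at 3-fold higher with CEP1 and 100% of the 50 planted at 6-fold. It took 10% of the 50 genes planted at 1.7-fold, and 0% of 16305 unplanted genes. The simulated noise was a chosen level, since noise between arrays cannot be measured with 1 array per group. Planted genes were all well above the median expression. These shares describe the rule under that setting and are not error rates on the deposited arrays. Of 200 unchanged lists, 5% stood apart, and of 50 lists shifted by 0.3 on the log2 scale, 92% did. Those simulated lists were larger than most lists tested here. Their values had no ties, whereas 54.6% of measured genes were equal on all 3 arrays. Neither share therefore carries over to the lists reported below. The alternatives tried were median centring, quantile normalization, removal of an intensity-dependent trend, other floors and fold thresholds, a pseudocount of 16 on the linear scale, the mean of a gene's probe sets, and other summaries of a list. The result of 1 gene family is not reported here. Calculations used Python 3.11 with numpy, pandas, scipy and statsmodels.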

Results

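The study asked which shoot genes respond to CEP1, a peptide that roots starved of nitrogen send to the shoot, and to loss of its receptor CEPR1. Cotyledon vascular tissue of 8-day-old seedlings was profiled in 3 states, with 1 array each: untreated wild type, wild type grown throughout with 1 µM CEP1, and the receptor mutant cepr1-1. There are no replicates, so every difference below is between 2 arrays and has no replicate check or p-value. Pearson correlations across the 16505 measured genes, which are not independent replicates, were 0.996 between the control and CEP1 arrays, 0.993 between the control and cepr1-1, and 0.989 between CEP1 and cepr1-1.

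With CEP1, 36 genes were at least 2-fold higher and 12 at least 2-fold lower than in the control, among 8596 genes above the floor. The glutaredoxins CEPD1 and CEPD2, small redox proteins known as shoot-to-root signals of nitrogen demand, were among the higher genes. CEPD1 (AT1G06830) was 7.46 on the log2 scale in the control and 9.00 with CEP1, 2.91-fold higher. CEPD2 (AT2G47880) was 4.06 and 5.79, 3.32-fold higher. The sugar transporter gene SWEET4 (AT3G28007) was 3.22-fold higher, at 6.64 and 8.33.

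Many of the genes with large differences are known here by locus. For a gene named by the size of its difference, only the values are given where the dimmer one lies below its array's median (3.07 for the control and CEP1 arrays, 3.11 for cepr1-1), since signal above background is not shown there. Members of the lists below are mostly given as differences or as equal. Of these, CEP2, CEP3, CEP4, CEP5, NRT2.5, ARR15, ARR16 and LBD16 lie under that level on all 3 arrays. So do UF3GT, UGT75C1, DFR, GH3.3, OPS, BHLH101, HSP22 and HSP17.6C. For such genes a difference of 0 does not show unchanged expression. AT3G27970 was 3.03 in the control and 8.10 with CEP1, and AT5G40310 was 3.68 and 7.39. AT5G46871 was 6.69-fold higher, AT3G22240 6.13-fold, AT3G47090 by 1.81 on the log2 scale and AT3G46880 3.14-fold. AT3G13130 was 2.11 and 4.17. AT1G63530 was 1.63 higher on the log2 scale and AT2G42520 was 1.55 higher. Among enzymes that add or remove sugars, the glycosyltransferases UGT73B5 (4.08-fold), UGT87A2 (5.50 in the control and 6.98 with CEP1), UGT73B4 (1.92 and 3.39) and UGT85A7 (2.58 and 3.93) were higher, and so was the beta-glucosidase gene BGLU28 (4.23 and 5.76). The remaining higher genes with a symbol of their own were ATSMC2, at 2.99 and 4.19, and SCPL32, at 2.75 and 3.79.

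AT2G18810, at 3.47 in the control and 1.4 with CEP1, was among the 12 lower genes. CC-type glutaredoxins of the family that holds CEPD1 were also among them, with AT1G03020 3.15-fold lower (6.23 and 4.58), AT3G21460 lower at 5.41 and 3.98 and AT3G62950 lower at 3.26 and 1.97. The iron-deficiency peptide gene IMA2 was 4.58 in the control and 3.51 with CEP1. AT4G36850 (-1.34 on the log2 scale), AT1G34040 (3.86 and 2.58), AT4G15430 (-1.27 on the log2 scale), AT4G32090 (-1.25), AT1G30060 (-1.11) and AT4G15710 (-1.02) follow, and AT5G44680 was 8.11 in the control and 7.11 with CEP1.

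Of the 9 fixed lists with enough named members, the iron deficiency list was outside the central 95% of random lists with CEP1. Its 4 measured members had a median difference of -0.61, with IMA1 at -0.89, the transcription factor gene BHLH101 at 2.02 and 1.69 and PYE equal on both arrays at 5.62. The 2 members at least 1.5-fold lower with CEP1 were IMA1 and IMA2, with neighbouring locus numbers, and signal shared between them was not tested. On the same array the guard cell markers GC1 and FAMA differed by -0.68 and -0.51, and the mesophyll list was below its random lists after quantile normalization and after trend removal. By chance 0.45 of 9 lists would lie outside. The 20 CC-type glutaredoxins went both ways, 2 higher and 6 lower by 1.5-fold or more, so that their median was 0 and not outside. By mean difference, -0.20, the family was below its random lists, which ranged from -0.07 to 0.10.

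The other lists were inside their random range with CEP1. The 5 CEP peptide genes had a median difference of 0, with CEP9 at -0.33, CEP4 at 0.19, CEP2 at -0.08, and CEP3 and CEP5 equal on both arrays. Primary nitrate response had a median of 0.06 over 3 genes (HHO2 at 0.27, HHO3 at 0.06), mesophyll -0.10 over 3 (RCA at -0.12, SBPASE at -0.10), and abscisic acid and cold response 0.05 over 4 (KIN1 at 3.80 and 2.91, COR15A at 0.38 on the log2 scale). Auxin response (6 genes, GH3.1 and GH3.3 among them), flavonoid synthesis (3, with DFR and UGT75C1) and the reference genes (4, with SAND and FBOX) had medians of 0.

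Lists with 1 or 2 named members give single values. The guard cell markers GC1 and FAMA differed by -0.41 and 0 in cepr1-1. The phloem sugar exporter SWEET11, at 11.5 in the control, differed by 0.03 and 0.06, and OPS was equal on all 3 arrays at 2.91. The nitrate transporter genes NRT2.5 (0.09 and 0.17) and NRT1.4 (-0.05 and -0.11), the cytokinin response genes ARR16 (0.19 and 0.25) and ARR15 (0 and -0.34), and the heat shock genes HSP22 and HSP17.6C (equal on all 3) were all under 1.5-fold. In the sulfate starvation list, BGLU28 was 0.77 higher in cepr1-1 too, whereas SDI2 was equal on all 3 arrays. The glucosinolate gene UGT74C1 differed by 0.67 with CEP1 and 0 in cepr1-1. The wound-response genes ZAT10 (0.38 and -0.48) and CML37 (-0.02 and -0.50), the sugar starvation gene KINBETA (-0.25 and 0.27) and the clock gene GI (0.25 and 0) complete these lists. With a pseudocount of 16, which damps dim genes, 18 genes were higher with CEP1 and 2 lower.

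**Figure D1:**
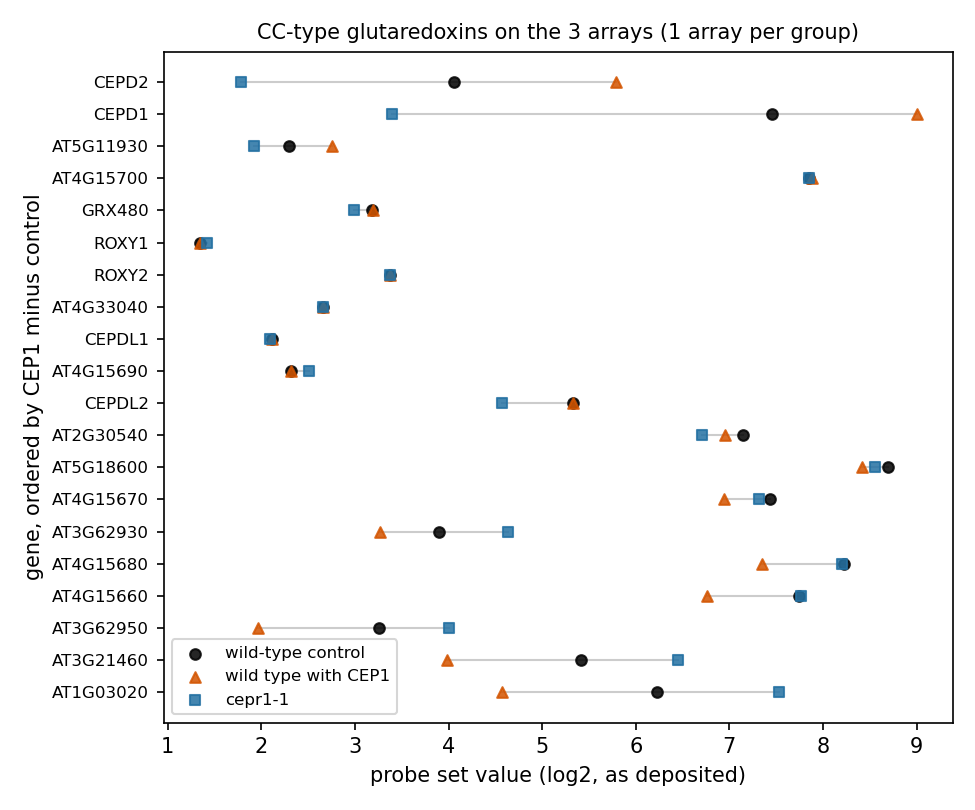
Log2 probe set values (x axis) of the 20 measured CC-type glutaredoxin genes (y axis, ordered by CEP1 minus control), 1 array per group: circles, wild-type control; triangles, wild type with CEP1; squares, cepr1-1. CEPD1 and CEPD2 run from cepr1-1 up to CEP1, whereas AT1G03020, AT3G21460, AT3G62950 and AT3G62930 run from CEP1 up to cepr1-1.

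In cepr1-1 the mutated gene CEPR1 has no named probe set here, so the genotype label could not be checked on the arrays. The ecotypes of the wild type and the mutant are not given in the sources used here, so a difference in background between them is not excluded for any gene of this comparison. CEPD1 had the largest difference of the mutant, at 7.46 in the control and 3.39 in cepr1-1, 16.7-fold lower. CEPD2 was 4.06 and 1.78, the second value well below the median of that array. Sugar transporter genes were lower too, SWEET13 at 5.95 and 4.14 and SWEET4 at 6.64 and 5.36. So were CLE44, which encodes a peptide that keeps vascular cells from becoming xylem (3.91 and 2.15), and the glucosinolate transporter gene GTR2 (10.5 and 9.04). CLE41, of the same family as CLE44 and brighter, was 7.93 in the control and 7.96 in cepr1-1. In all, 49 genes were at least 2-fold lower and 30 at least 2-fold higher, among 8644 above the floor.

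Further lower genes were AT5G46871 (4.98 in the control and 2.05 in cepr1-1), AT1G48720 (4.70 in the control and 1.78 in cepr1-1), AT3G46880 (7.18-fold), AT3G24230 (6.65-fold), AT4G13180 (5.87 and 3.32), AT2G18810 (3.47 and 1.27), AT1G67860 (3.93-fold), AT1G67865 (3.57-fold) and AT2G25510 (4.01 and 2.2). UGT73B5 was 2.86-fold lower, the gene ACA.l was 5.07 and 3.46, and the cold-induced gene KIN1 was 3.80 and 2.48. Among higher genes, AT4G15990 was 2.66 in the control and 5.24 in cepr1-1. AT5G53720 was 1.63 and 3.41, AT3G32980 1.93 and 3.62, AT4G28360 2.67 and 4.25, AT5G05965 1.87 and 3.37, SCRL26 1.81 and 3.28, and AT5G39000 2.66 and 3.79. AT1G03020 was 2.46-fold higher, and AT1G03106 was 1.17 higher on the log2 scale, AT2G15880 1.13, AT1G05140 1.13 and AT5G15780 1.13. NdhL, a subunit of a chloroplast electron transport complex, was 6.82 and 7.90, UGT85A7 was 2.58 and 3.61, and the phosphatase gene TOPP7 was 3.11 and 4.17. AT3G21460, at 5.41 and 6.45, was 2.06-fold higher.

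Of the 9 fixed lists, the mesophyll and iron deficiency lists stood apart in cepr1-1. The CC-type glutaredoxins had 4 members higher and 3 lower by 1.5-fold or more. Their median of -0.01 passes the rule as well, but the central 95% of random medians are tied at 0. Since the members also went both ways, this median is not read as a shift of the family. By mean difference, -0.21, the family was below its random lists, which ranged from -0.13 to 0.08, with CEPD1 at -4.07 and CEPD2 at -2.28. Of the CEPD-like members, CEPDL2 was 5.33 in the control and 4.57 in cepr1-1, and CEPDL1 was 2.12 and 2.09. With CEP1, CEPDL2 and CEPDL1 were equal to the control, and CEPDL1 lies below the median on all 3 arrays. The 3 mesophyll markers, of 19 listed, had a median of 0.21, with SBPASE at 0.69, RCA at 0.21 and PRK at -0.03. By its median and mean, this list of another leaf cell type was higher on the array on which the genes above were lower. By the share of members 1.5-fold apart it did not stand apart, and a difference in tissue mix was not tested. The iron deficiency list had a median of 0.12, with IMA2 at 0.35 and IMA1 at 0.24, and PYE and BHLH101 equal on both arrays. The other 6 were inside: CEP peptides 0, primary nitrate response 0, auxin response 0 (GH3.5 at -0.44, LBD16 at 0.06), flavonoid synthesis 0 (UF3GT at 0.05), abscisic acid and cold response -0.08 (COR15A at -0.16) and reference genes -0.07 (FBOX at -0.26, UBC21 at -0.14). By its mean, -0.37, the abscisic acid and cold list lay below its random lists (-0.30 to 0.19), with KIN1 at the values above. The iron deficiency list no longer stood apart by its mean or without matching. With a pseudocount of 16, 2 genes were higher in cepr1-1 and 14 lower.

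Of 8547 genes above the floor in both comparisons, 30 were higher with CEP1 and lower in cepr1-1, at 1.5-fold or more each way. CEPD1, CEPD2, AT5G46871, AT3G46880, UGT73B5, AT1G67860, SWEET4, AT3G22240 and AT2G05632 ranked first by the smaller of a gene's 2 differences. CLE44, the expansin gene EXPA9 and the sulfate activation gene APS3 were also among the 30. The mirror pattern, lower with CEP1 and higher in cepr1-1, held for 10 genes, of which 4 are CC-type glutaredoxins: AT1G03020, AT3G21460, AT3G62950 and AT3G62930.

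Permuting the 3 values within each gene gave on average 7.46 and 7.42 genes, and at most 19 and 17. Independent lists of the same sizes would share 2.58 and 0.807 genes. Another 35 genes differed the same way, against 140.5 on average after permutation, with 12 higher in both (1.04 from independent lists) and 23 lower in both (1.99). Here AT2G18810, AT1G34040, AT4G15430, AT1G48720, AT4G31000, AT3G29639 and KIN1 were lower, and AT4G28360, AT1G61330 and UGT85A7 higher. A shared control array produces such genes by itself, and the permutation does not show how many. Part of the excess of these same-way genes over independent lists may come from the shared control. An error in that control enters both differences with the same sign, so by itself it gives no opposite pattern.

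Over the 3 arrays, 172 genes spanned at least 2-fold, and 159 of them had 3 different values. The control lay in the middle for 125 of the 159 genes, 78.6% (exact 95% binomial interval 71.4 to 84.7, which treats genes as independent), the CEP1 array for 24 and cepr1-1 for 10. Permuted values put the control in the middle in 31.9% of genes. Among the 149 genes with the control or the CEP1 array in the middle, the control was the middle in 83.9%. Across all measured genes the 2 sets of differences had a Pearson correlation of 0.05 and a covariance of 0.0021, where permuted values gave 0.498 and 0.0255. Among genes above the floor in both comparisons the correlation was -0.0423, with permuted values at 0.520.

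**Figure D2:**
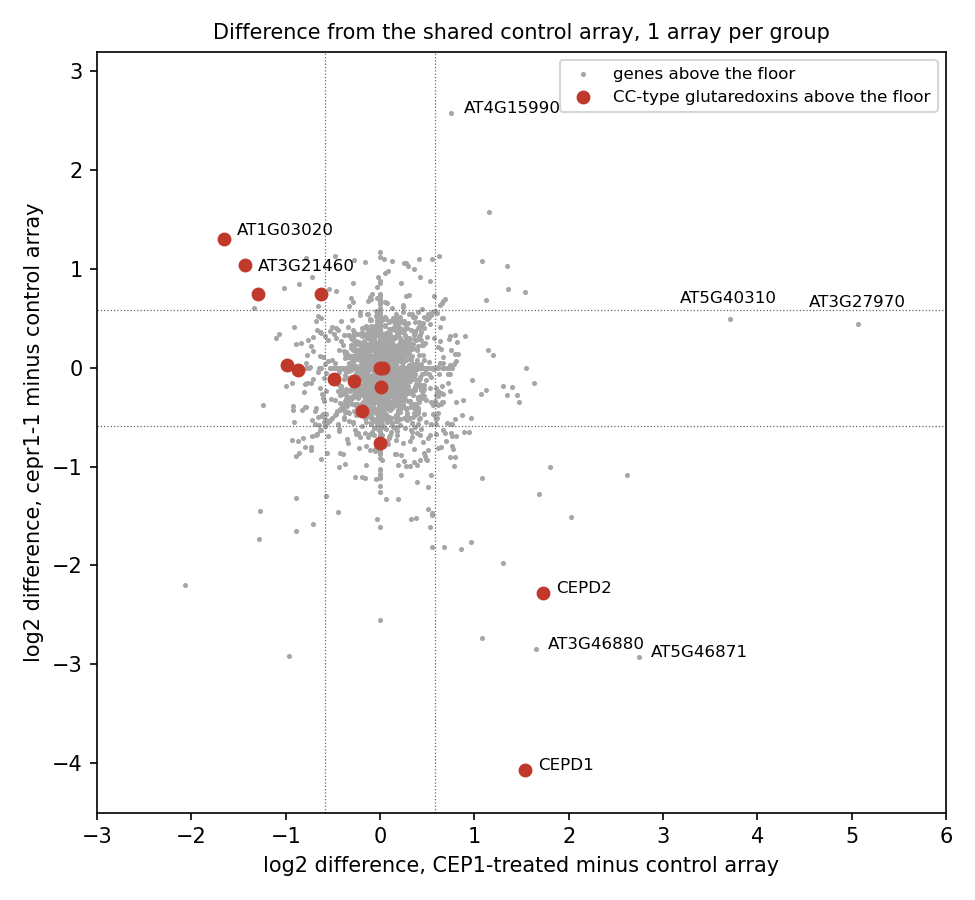
Log2 difference from the control array with CEP1 (x axis) and in cepr1-1 (y axis) for the 8547 genes above the floor in both comparisons, 1 array per group; red points are CC-type glutaredoxins and dotted lines mark 1.5-fold. CEPD1, CEPD2, AT5G46871 and AT3G46880 lie far to the lower right, and AT1G03020 and AT3G21460 to the upper left.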

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

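The tests on identical values and on the glutaredoxins were chosen after those results were seen, and the test on neighbouring genes was set before its result. The probe sets that have no gene name here were not part of any comparison. Their differences are between single arrays and were not tested against noise. Above the floor, 373 of 10061 were at least 2-fold higher with CEP1 and 273 lower, and of 10194, 497 were at least 2-fold higher in cepr1-1 and 389 lower. That is 3.71% and 2.71%, and 4.88% and 3.82%, whereas 0.558% of named genes were 2-fold different with CEP1 and 0.914% in cepr1-1. A subset of 7083 has IDs below the lowest listed one, and of these 0.155% were equal on all 3 arrays. Above the floor, 38.8% of that subset were 2-fold different with CEP1 and 41.9% in cepr1-1, and what its probe sets measure is not given in the sources used here. Without that subset, 3.84% of the unnamed probe sets were 2-fold different with CEP1 and 5.64% in cepr1-1.

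Of the 20 measured CC-type glutaredoxins, 6 differed by 1.5-fold or more in both comparisons, and these 6 had opposite signs in the comparisons; the others include members with the same sign or no difference. Hybridisation shared across the whole family would move the 6 together, so it alone does not give 2 (CEPD1 and CEPD2) against the rest, and an error of the control array alone would give each the same sign in both comparisons; both statements rest on the values that drew attention to the family, not on a separate test. All (100%) were at or above the control array's median. On that array this argues against dim signal for CEPD1, AT1G03020 and AT3G21460, at 7.46, 6.23 and 5.41. It does so less for AT3G62950, at 3.26, near that median. The check does not cover the other arrays. CEPD2 was 1.78 in cepr1-1 and AT3G62950 was 1.97 with CEP1, each below the median of its array. Sharing between close copies is left open: without the 5 tandem copies AT4G15660 to AT4G15700, 2 members were higher and 4 lower with CEP1. Those 4 include AT3G62930 and AT3G62950, which also have close locus numbers, and signal shared between them was not tested. A response through CEPR1 may account for the pattern as a hypothesis, and a difference in dissection or growth between single plates cannot be separated from the groups.

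Of measured genes, 54.6% had the same value on all 3 arrays. A signal floor would limit this to dim genes, yet it held for 40.7% of the brightest 25% of genes. Simulated probe sets of 11 probes without any change, summarised over 3 arrays by median polish, were identical in 43.1% of cases, consistent with that summary as a candidate cause. The share depends on the assumed number of probes (0% at 4, 8.95% at 8 and 57.6% at 22), and neither that number nor the method is given in the sources used here, so the explanation stays open; a biological one was not tested. If it holds, a difference of 0 means a small difference rather than none.

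The 79 genes at least 2-fold different in cepr1-1 could come from a chromosome segment linked to the mutation. Among the 200 measured genes around CEPR1, 6 differed by 1.5-fold or more, 1.01 times the share elsewhere, with an interval of 0.373 to 2.16 for the ratio. Among genes above the floor it was 1.77, with an interval of 0.926 to 3.02, so a moderate local excess cannot be told apart from none. Elsewhere, the densest run of 100 neighbours held 9 such genes, more than in 15 of 100 random gene orders. The densest run of random orders had a median of 9 and a maximum of 13. This argues against another segment dense enough to exceed those, whereas a shorter or weaker segment could be missed. A difference in ecotype spread over the genome is not addressed by these tests and stays open, as does an effect of the mutation through the receptor.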

How the results depend on the processing

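No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Median centring (which moves nothing with CEP1), quantile normalization and removal of the intensity trend kept the 7 gene counts within 1.5 times and the share with the control in the middle within its interval. They moved the median difference by at most 0.035 in size on the log2 scale in cepr1-1 (-0.035). The counts follow the floor and the threshold by construction. With a floor at the 75th percentile, 23 genes were higher and 7 lower with CEP1, 13 higher and 32 lower in cepr1-1, 5 lower with CEP1 and higher in cepr1-1, and 10 differed the same way in both. Without a floor, 22 were lower with CEP1, 54 higher in cepr1-1 and 61 the same way in both. At 1.5-fold the counts were 135 and 92 with CEP1 and 111 and 185 in cepr1-1, and at 3-fold 11 and 2, and 3 and 17. With the pseudocount of 16 they were 18 and 2, and 2 and 14, because dim genes are damped. At 2-fold in both comparisons, 10 genes were higher with CEP1 and lower in cepr1-1, 2 the mirror image and 6 the same way. The control was in the middle in 70.6% of genes without a floor, 88.5% with the higher floor and 68.9% at a range of 1.5-fold. With CEP1, 2 lists stood apart instead of 1 by the mean, among members above the floor, after trend removal, after quantile normalization and by the share of members 1.5-fold apart either way (chosen after the data were seen). The added list was the mesophyll markers, lower, after trend removal and quantile normalization, and the glutaredoxins otherwise. In cepr1-1 the share summary gave 1 list, the glutaredoxins (35% of members 1.5-fold apart), instead of 3. Those 3 count the glutaredoxins' median of -0.01, which no longer passed among members above the floor, after quantile normalization or after trend removal. By its mean, -0.21, the family was below its random lists in cepr1-1. The cause was not tested. The correlation of the comparisons was 0.14 by Spearman, -0.0423 above the floor, 0.0730 after quantile normalization and -0.0447 among genes with 3 different values (the last also chosen afterwards), so its sign is not settled. Of 76 named differences of 2-fold or more, 75 stayed at 2-fold after median centring, 75 after quantile normalization, 76 after trend removal and 30 with the pseudocount, and 0 changed direction. The arrays' signal over background is unknown, so differences of dim genes are the least certain.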

Other observations

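The groups in this part were formed after the data were seen, from gene symbols that share their letters, and 55 such families with at least 5 measured genes were set against random lists by their mean, where 2.75 would lie outside by chance. With CEP1, 4 did, among them UGT, PDF and SWEET. The PDF mean (0.17 over 10 genes) comes from 4 members that are all below the floor, and the SWEET mean (0.10 over 14) rests on SWEET4, with 9 members equal on both arrays. By the share of members 1.5-fold apart either way, 2 lay outside with CEP1, UGT and EXPA, and 0 in cepr1-1. The UDP-glycosyltransferases, which attach sugars to hormones and other small molecules, had a mean difference of 0.19 over 51 genes, against random means of -0.05 to 0.04. Of these, 7 were at least 1.5-fold higher and 0 at least 1.5-fold lower: UGT73B5, UGT87A2, UGT73B4, UGT85A7, UGT76E11 (2.45 in the control and 3.32 with CEP1), UGT76E1 (1.00 and 1.78) and UGT73B2 (4.51 and 5.15). Under quantile normalization (0.19) and trend removal (0.20) the UGT mean was above its random lists too, and median centring moves nothing with CEP1. Of the 7, UGT73B4, UGT85A7, UGT76E11 and UGT76E1 were below the median on the control array, and UGT76E1 was below the floor. In cepr1-1 the UGT mean was 0.05, inside its random lists (-0.04 to 0.07). There 3 members were at least 1.5-fold higher, UGT76E1 and UGT85A7 among them, and 1 lower, UGT73B5. Copies such as UGT73B4 and UGT73B5 are close relatives whose probes can share signal.

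In cepr1-1, 7 families lay outside by their mean, 3 lower and 4 higher. The higher ones were CYP (0.10 over 28 genes) and OTP (0.19 over 7), which lay just above the upper ends of their random means, 0.102 and 0.186, SCRL (0.18 over 12), which rests on SCRL26, below the median in the control, and RPS (0.11 over 7, all chloroplast-encoded), and RPS no longer lay outside after quantile normalization or trend removal. The 14 SWEET sugar transporters had a mean of -0.23, carried mostly by SWEET13 and SWEET4, while 9 members were equal on both arrays. The 10 PUB ubiquitin ligases had a mean of -0.23, with PUB24 at -0.71, PUB23 at -0.55 and PUB43 at 3.25 in the control and 2.44 in cepr1-1. The 9 CLE peptides had a mean of -0.22, which rests on CLE44, whereas the brighter CLE41 differed by 0.02. The SWEET, PUB and CLE means stayed negative under the 3 scalings. The 63 chloroplast-encoded genes had a mean of 0.04 in cepr1-1, above random lists of equally bright genes (-0.14 to -0.01), and with CEP1 of -0.01, inside them. Under median centring their mean was 0.0050, and it was above its random lists there as well.

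On the control array the 16505 measured genes took 5500 different values. The commonest was 1.78, held by 622 genes, and CEPD2 had that level in cepr1-1.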
